A study of Mus musculus with 6 samples.

How the data were processed

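RNA-seq libraries of TM4 cells, an established mouse Sertoli cell line, were compared between 3 control libraries and 3 libraries of cells kept in 100 nM aluminium chloride (AlCl3) for 30 days. Control libraries were also taken at day 30, per the labels. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The extraction text of the labels speaks of retinas, while the cell line and cell type labels give TM4 Sertoli cells, and retina markers were therefore included among the gene lists.

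The deposited values are FPKM, fragments or reads per kilobase of gene and per library size, made by the authors, as read from the name of the table and from its values. Reads were aligned with HISAT2 2.1.0 to GRCm38, per the submitters' processing notes. The read counter, the annotation, the strand setting and any filter are not given in the sources used here. The table held 24354 genes by Ensembl identifier, with 1 column per library. Symbols, coordinates and lengths came from GENCODE mouse release 21 (GRCm38), which held 24300 of the identifiers and lacked 54.

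The steps of the low FPKM values gave back whole reads. With the summed exon lengths of GENCODE, 98.4% of genes came out whole in each library within a tolerance of 0.01 reads, 368 further genes came out whole with a step of their own, and 21 did not. Recovered reads in genes ranged from 13469273 in AlCl3 2 to 17462067 in AlCl3 1. A single read in a gene of 1 kb was worth between 0.0568 and 0.0736 FPKM, and a floor of 3 reads between 0.170 and 0.221 FPKM. These floors cover counting error only. No pair of libraries was identical, and within each group the recovered reads differed by more than sampling noise, with a chi-square per gene between 11.8 and 60.5 in the 6 pairs of replicates.

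Genes with a mean FPKM of at least 1 over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a variance trend and no covariate. Adjusted p-values are Benjamini-Hochberg values over all genes tested, two-sided, with a threshold of 0.05. Fold changes on this scale understate the change of genes with low values. FPKM values are given as mean ± SD with 3 libraries per group. Exact permutation tests of 3 against 3 values cannot give a two-sided p under 0.1.

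Before the data were examined, 24 gene lists were fixed. They covered tight junctions and the blood-testis barrier, adherens and gap junctions and focal contacts, Slc25 mitochondrial carriers, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, NRF2 and antioxidant genes, metallothioneins and metal ion handling, the unfolded protein and integrated stress response, p53 targets and apoptosis, cell cycle and DNA replication, type I interferon response, NF-kB and cytokines, extracellular matrix and TGF-beta, cholesterol synthesis, glycolysis and hypoxia, autophagy and lysosome, immediate early genes and cytosolic ribosomal proteins. The others were markers of Sertoli cells, Leydig cells, peritubular myoid and smooth muscle cells, germ cells, macrophages and leukocytes, and retina. Lists with at least 5 genes tested went through camera in limma with a preset correlation of 0.01, camera with an estimated correlation, and fry. List p-values were adjusted over the lists. Counts adjusted over the list alone are given beside the counts over all genes. Aldoa stands in the table under 2 identifiers, which were tested as separate genes.

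The rule for named genes was fixed at the same time. It took the adenine nucleotide translocators Slc25a5, Slc25a4 and Slc25a31, the 12 highest and 12 lowest log2 fold changes among genes past the threshold whose groups did not overlap, leaving out predicted and unnamed genes, up to 4 members of each list with the smallest p, and the claudin, occludin and zonula occludens genes with the highest mean FPKM, up to 5. Not every gene that the rule took is used here. Ocln, below the filter, is given as a further junction gene. Other genes named outside this rule are marked as chosen after their values were seen.

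The limma step was tested on simulated data, with counts drawn for the real genes at the libraries' depths and 200 genes changed in each of 20 simulations of AlCl3 against control over 11115 genes on average. It recovered 3.45% of genes changed 1.25-fold, 37.6% at 1.5-fold, 95.0% at 2-fold and 100% at 4-fold. False calls made up 9.78% of all calls, above the 5% aimed for. They lay among genes with fewer than 200 reads on average, where 39.5% of the calls were false, against 0.616% elsewhere. This division, and the use of 20 simulations after a first run with 1, were chosen after the false share was seen. A false share depends on how many genes truly change. Beside a changed list, the simulation changed only 200 genes, with a single dispersion for all genes, while 61.3% of genes passed in the real libraries. The share of false calls among the real calls therefore cannot be read from it. Camera with the preset correlation called 20 of 20 changed lists and 0 of 400 unchanged lists. Each gene was drawn independently, so this could not test the preset correlation. In the real libraries the estimated correlation ranged from -0.034 for NRF2 and antioxidant genes to 0.64 for cytosolic ribosomal protein genes, with 0.57 for tight junction genes. For NF-kB and cytokine genes it was 0.0070, below the preset value. That list still went from a camera adjusted p of 0.010 to 0.34 with an estimated correlation. A higher correlation therefore does not account for every call lost in that test.

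Of the 2444 genes tested with fewer than 200 reads on average, 1348 passed the threshold. With limma-voom on the recovered reads, an alternative chosen after seeing the data, 1255 of these passed in the same direction. Voom was not run on the simulated data and used the same libraries, so this overlap cannot show that the calls are true. The named genes below that depth were S100g, Mmp10, Plac8, Cgn, Cxadr, Pard6b, Slc25a42, Dhh, Inha, Fdx1, Gdf15, Mmp3 and Cd68. Each of them except Cd68 also passed with voom.

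The longest transcript of each named gene and mitochondrial mRNA was searched with blastn 2.17.0 against all GENCODE transcripts for matches of at least 95% identity over at least 200 bases in other genes. Reads of genes with such matches can be split or lost in counting. The alternatives were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 5, rescaling to TPM, median-ratio scaling, quantile normalization, the replicate number as a block, leaving out each library, other variance models, array weights, an added fold limit and other list tests. Removal of the trend with GC content and transcript length by loess with a span of 0.3 and voom were added after seeing the data, as were 4 gene lists, given among the other observations. A scan of 103 families of genes sharing a symbol stem was also made after seeing the data, 17 passed in camera with the preset correlation, 0 with an estimated correlation (4 below an unadjusted p of 0.05) and 57 in fry. No family was named on this basis. The figures were drawn with matplotlib 3.10.9 and the remaining steps used Python 3.11.15.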

Results

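Gene expression was measured by RNA-seq in TM4 cells, a mouse line of Sertoli cells, the somatic cells that surround germ cells in the seminiferous tubule and form the blood-testis barrier. The libraries comprised 3 of control cells and 3 of cells kept in 100 nM AlCl3, all taken at day 30. Reads in genes, as recovered from the FPKM values, numbered 16485603, 16751139 and 17256291 in control 1 to 3 and 17462067, 13469273 and 17011098 in AlCl3 1 to 3. The design asks which mRNAs differ after long exposure to AlCl3, and the study's title names Slc25a5 and tight junctions.

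Slc25a5, which encodes an adenine nucleotide translocator of the inner mitochondrial membrane, rose 7.10-fold in AlCl3. Its level was 73.8 ± 4.61 FPKM in controls and 525 ± 45.5 FPKM in AlCl3 (SD, n = 3 each), and all 3 AlCl3 values lay above all 3 control values. Its log2 fold change of 2.81 (SE 0.13), taken on FPKM + 1, ranked 7 among the 11202 genes tested (limma, Benjamini-Hochberg adjusted p = 1.8e-06). Some genes ranked below it on that scale rose more by the ratio of mean FPKM, such as Mmp10 (27.1-fold), Il1rl1 (9.69-fold) and Dhx9 (8.80-fold). The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 values allow. Slc25a5 (ENSMUSG00000016319) lies on the plus strand of chromosome X from 36795651 to 36798807 in GRCm38. Its near-identical annotated copies, Gm5529 and Gm5560, held 93 reads in controls and 538 in AlCl3, against 6179 and 41703 for Slc25a5 itself. Slc25a4, the related translocator on chromosome 8, stood at 330 ± 57.7 FPKM in controls and 444 ± 36.0 in AlCl3. It rose by a log2 fold change of 0.44 (limma adjusted p = 0.047), and this call was lost without any 1 of control 2, control 3, AlCl3 1, AlCl3 2 or AlCl3 3, with adjusted p between 0.053 and 0.16, as well as under median-ratio scaling (0.083) and with no filter on low values (0.11). Slc25a31 was not analysed here.

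**Figure D1:**
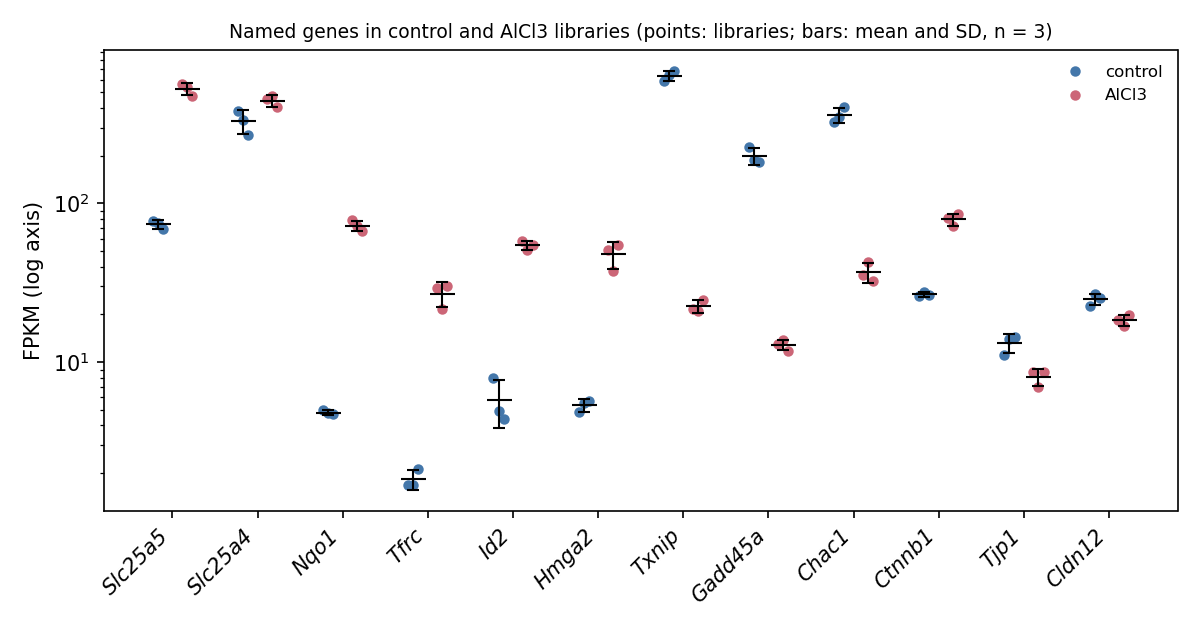
FPKM of 12 named genes on a log axis in the 3 control libraries and the 3 AlCl3 libraries, with points for libraries and bars for the mean and SD. Slc25a5 rose from a mean of 73.8 to 525 FPKM while Txnip fell from 638 to 22.5.

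The largest rises after AlCl3 were found in Nqo1, Prl2c2, Tfrc, Id2, Hmga2, Atoh8, Slc25a5, Dhx9, Ebna1bp2, Mmp10, Nasp and Il1rl1. Nqo1, which encodes a quinone reductase, went from 4.82 ± 0.159 to 72.5 ± 5.40 FPKM, a log2 fold change of 3.66 (SE 0.11). Prl2c2, a member of the prolactin family, reached a log2 fold change of 3.41. Prl2c3 and Prl2c5, which are nearly identical to it, held few reads. Tfrc, the transferrin receptor, rose from 1.83 ± 0.264 to 27.0 ± 4.81 FPKM, a log2 fold change of 3.30. Log2 fold changes were 3.07 for Id2, an inhibitor of helix-loop-helix factors, 2.92 for the chromatin protein gene Hmga2 and 2.89 for Atoh8. Dhx9, an RNA helicase gene, Ebna1bp2, a nucleolar protein gene, and Mmp10, a secreted protease gene, rose by 2.77, 2.76 and 2.73. Nasp, a histone chaperone gene, and Il1rl1, which encodes the receptor of interleukin 33, rose by 2.70 and 2.66. Parts of the longest Nasp transcript match other genes, so its level is less certain.

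On the same scale, the largest falls were found in Txnip, S100g, Gadd45a, Angptl6, Ptx3, Map3k7cl, Angpt4, Plac8, Chac1, Fbxo2, Cdsn and Azin2. Txnip, which encodes thioredoxin-interacting protein, dropped from 638 ± 45.2 to 22.5 ± 2.05 FPKM, 28.4-fold lower and a log2 fold change of -4.77 (SE 0.13). S100g, a calcium-binding protein gene, went from 39.7 ± 5.45 to 0.632 ± 0.185 FPKM, a log2 fold change of -4.64. Gadd45a, a growth arrest gene, fell from 198 ± 24.0 to 12.9 ± 0.964 FPKM, and Chac1, a glutathione-degrading enzyme induced by amino acid stress, from 359 ± 39.6 to 36.9 ± 5.35 FPKM. Log2 fold changes were -3.70 for Angptl6, -3.63 for the pentraxin gene Ptx3, -3.36 for Map3k7cl and -3.34 for Angpt4. Those of Plac8, Fbxo2, Cdsn and Azin2 lay at -3.30, -3.24, -3.22 and -3.18. The adjusted p-values of these 24 genes ran from 2.2e-07 to 4.0e-06 (limma, Benjamini-Hochberg).

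In all, 6869 of the 11202 genes passed the threshold (61.3%), 3490 of them higher and 3379 lower in AlCl3. An absolute log2 fold change of FPKM + 1 of at least 1 was reached by 2387 of these genes, 1207 higher and 1180 lower. This leaves out genes with low values whose FPKM changed more than 2-fold. Groups did not overlap in 66.1% of genes, where chance gives 10%. The first principal component held 83.8% of the variance and separated the groups. Correlations of log2 values were 0.978 to 0.993 within groups and 0.874 to 0.904 between them. Fold changes followed the GC content of the transcripts, with median log2 values from 0.33 in the tenth of genes lowest in GC to -0.53 in the tenth highest.

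Of the 24 gene lists, 20 had enough genes to test, and 9 passed with the preset correlation of camera. With an estimated correlation 0 of 20 passed in camera, 2 of them lying below an unadjusted p of 0.05, and fry, which asks only whether members move on balance in 1 direction, passed 15. Unlike camera with the preset correlation, fry passed the tight junction, Slc25 carrier, Sertoli cell, NRF2, metal ion, p53 and autophagy lists. It did not pass the cytosolic ribosomal protein list. Other splits of the same 6 libraries gave between 2 and 10 lists past the preset-correlation threshold.

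**Figure D2:**
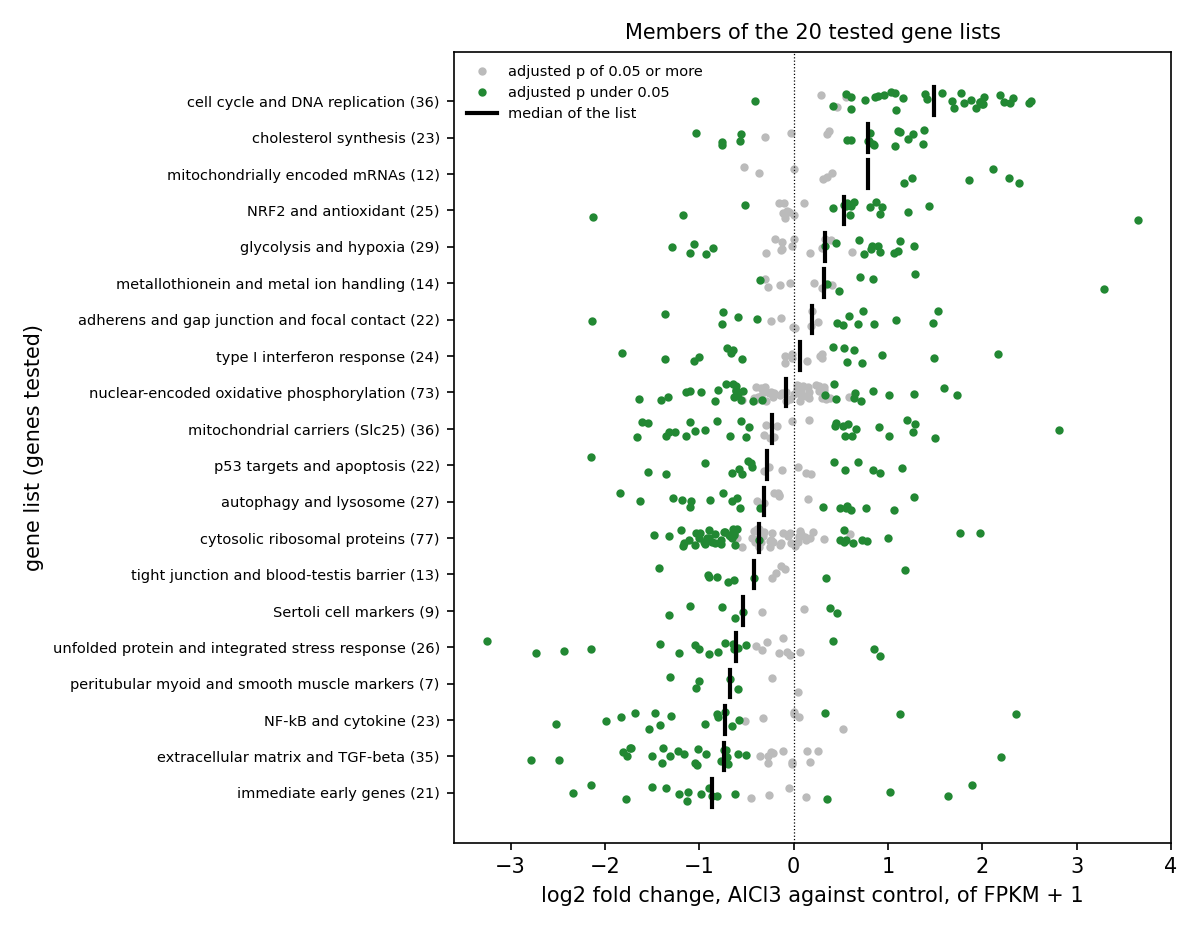
Log2 fold changes of FPKM + 1, AlCl3 against control, for the members of the 20 tested lists. Each point is a gene, coloured by whether its adjusted p lay under 0.05, and black bars mark list medians, from -0.87 for immediate early genes to 1.49 for cell cycle genes.

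Junction genes moved in both directions. In the tight junction list 7 of 13 genes fell and 2 rose, with the same counts adjusted over the list alone. Cgn, which encodes the junction plaque protein cingulin, fell 5.53-fold from 3.32 ± 0.404 FPKM (log2 fold change -1.43, adjusted p = 1.6e-05 in limma). Cxadr, a junctional adhesion receptor gene, fell by 0.81 on the log2 scale and the polarity gene Pard6b by 0.91. Tjp1, which encodes the plaque protein ZO-1, fell from 13.2 ± 1.78 to 8.11 ± 0.978 FPKM (log2 fold change -0.64, limma adjusted p = 0.0033). Cldn12, the single claudin gene tested, fell from 24.9 ± 2.02 to 18.4 ± 1.48 FPKM (-0.42, limma adjusted p = 0.012), a call lost without control 2 (0.060) and after rescaling to TPM (0.13), with adjusted p from 2.6e-04 to 0.13 over all alternatives. Ocln stood at 0.0554 FPKM in controls and 0.103 in AlCl3, below the filter. The list as a whole had a median log2 fold change of -0.42 (camera adjusted p = 0.069, adjusted p = 0.66 with an estimated correlation). It passed without control 1 (camera adjusted p = 0.038) and in fry (fry adjusted p = 0.021). Its median ranged from -0.64 to -0.11 over the alternatives, and shrank to -0.11 with no filter on low values and to -0.19 with a mean FPKM of at least 5.

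Among adherens and gap junction and focal contact genes 9 of 22 rose and 6 fell, also when adjusted over the list alone. Ctnnb1 (beta-catenin) rose from 26.8 ± 0.872 to 79.4 ± 6.98 FPKM and Cdh2 (N-cadherin) by a log2 fold change of 1.48. Nectin2, an adhesion molecule of Sertoli cells, fell from 43.2 ± 7.49 to 9.10 ± 1.94 FPKM and Zyx (zyxin) by 1.36 on the log2 scale. The list median was 0.19 (camera adjusted p = 0.49), and 0.071 without control 1 and 0.032 with no filter on low values. Of 30 Sertoli cell markers 9 were tested, and several well known ones lay below the filter, such as Wt1 at 0.146 and Amh at 0.0470 FPKM in controls. Of the 9 tested, 5 fell and 2 rose, with the same counts adjusted over the list alone and a camera adjusted p of 0.21. Dhh, a hedgehog ligand gene that overlaps Rhebl1, fell from 1.90 ± 0.208 to 0.160 ± 0.006 FPKM. The inhibin gene Inha fell by 1.09 and the transcription factor gene Gata4 by 0.76 on the log2 scale, with values of -0.51 and -0.33 after removal of the GC and length trend. Inhbb fell by 0.62, but after that removal its log2 fold change was -0.02 (limma adjusted p = 0.82), the other alternatives giving adjusted p between 9.4e-04 and 0.027.

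Markers of other cell types stayed low or moved with the group in part. Of 10 retina markers and 7 germ cell markers measured, 0 reached the filter, the highest mean being 0.135 FPKM for retina and 0.175 FPKM for germ cells. Among Leydig cell markers 2 were tested, Fdx1 (-0.48) and Nr2f2 (-0.37), and both were lower at adjusted p of 0.017 and 0.045 (limma). Both calls were lost after rescaling to TPM (0.068 and 0.26) and with no filter on low values (0.055 and 0.093), and that of Nr2f2 also without control 2, control 3, AlCl3 1 or AlCl3 2 (0.12, 0.14, 0.093 and 0.12). Adjusted over the list alone both passed. Of 13 macrophage and leukocyte markers 2 were tested. Cd14 rose from 7.35 ± 0.779 to 30.7 ± 1.11 FPKM and Cd68 was at 1.16 ± 0.266 and 1.19 ± 0.313 FPKM, 1 of 2 passing over the list alone as well. Csf1r, Fcgr1, Aif1 and Lyz2 lay below the filter, the highest group mean among them being 0.195 FPKM for Lyz2 in controls. In the peritubular myoid and smooth muscle list 5 of 7 genes fell and 0 rose, likewise adjusted over the list alone, with a median of -0.68 (camera adjusted p = 0.026, adjusted p = 0.60 with an estimated correlation, and 0.070 after removal of the GC and length trend). Acta2 (smooth muscle actin) fell from 454 ± 14.0 to 183 ± 14.9 FPKM, Myl9 by 1.04 and Smtn by 1.00 on the log2 scale, with values of -0.69 and -0.40 for the latter pair after removal of that trend.

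Cell cycle and DNA replication genes rose together, 32 of 36 being higher and 1 lower in AlCl3, or 33 and 1 adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, rose from 14.4 ± 0.791 to 85.5 ± 4.69 FPKM (log2 fold change 2.49, SE 0.11, adjusted p = 1.6e-06 in limma). The replicative helicase gene Mcm7 rose by 2.23, the licensing factor gene Cdc6 by 2.19 and Ccna2 (cyclin A2) by 1.98 on the log2 scale. Mcm7 and Ccna2 overlap Ap4m1 and Exosc9, which held far fewer reads. The list median was 1.49 (camera adjusted p = 5.4e-11, adjusted p = 0.34 with an estimated correlation). Among p53 targets and apoptosis genes 10 of 22 fell and 6 rose, or 11 and 6 adjusted over the list alone (camera adjusted p = 0.33). Btg2, an antiproliferative gene, fell from 16.6 ± 1.37 to 2.97 ± 0.610 FPKM, Gdf15 by 1.54 (-0.85 after removal of the GC and length trend) and Plk2 by 1.35 on the log2 scale, while the proapoptotic gene Bcl2l11 rose by 1.15.

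In the unfolded protein and integrated stress response list 15 of 26 genes fell and 3 rose, with the same counts adjusted over the list alone. Trib3 fell from 474 ± 33.8 to 71.3 ± 14.0 FPKM, Ddit3 (CHOP) from 81.5 ± 11.3 to 17.5 ± 0.676 FPKM and Ppp1r15a, the inducible phosphatase subunit gene of the response, from 140 ± 13.5 to 25.1 ± 4.68 FPKM. The median was -0.61 (camera adjusted p = 0.0039, adjusted p = 0.60 with an estimated correlation). Among immediate early genes 13 of 21 fell and 4 rose, adjusted over the list alone as well. Zfp36, an mRNA decay factor gene, fell by 2.33, Fos by 2.15 and Ier2 by 1.77 (-1.11 after removal of the GC and length trend) on the log2 scale, whereas Fosl1, which overlaps Ccdc85b, rose by a log2 fold change of 1.89. Their median was -0.87 (camera adjusted p = 0.019, adjusted p = 0.64 with an estimated correlation, and 0.10 after removal of the GC and length trend).

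NF-kB and cytokine genes were lower in 14 of 23 cases and higher in 3, with the same counts adjusted over the list alone. The complement gene C3 fell from 31.5 ± 6.55 to 7.06 ± 0.530 FPKM, the chemokine gene Cxcl12 by 1.68 and Relb by 1.47 on the log2 scale. Il33 went the other way, from 4.01 ± 0.471 to 24.8 ± 2.76 FPKM. The median was -0.73 (camera adjusted p = 0.010, adjusted p = 0.34 with an estimated correlation). Type I interferon response genes were divided, 8 of 24 rising and 8 falling, also when adjusted over the list alone (median 0.07, camera adjusted p = 0.89). Ifit1 rose from 25.6 ± 3.24 to 118 ± 9.22 FPKM and Usp18 by a log2 fold change of 1.49, while Zbp1 fell by 1.82 and Irf7 by 1.05 on the log2 scale.

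Extracellular matrix and TGF-beta genes were mostly lower, 23 of 35 falling and 1 rising, counts that were the same adjusted over the list alone. Ccn2, a matricellular growth factor gene, fell from 174 ± 35.8 to 24.1 ± 1.81 FPKM, the collagen gene Col5a2 by 1.74 on the log2 scale and the metalloproteinase inhibitor gene Timp3 from 3.34 ± 0.371 to 0.308 ± 0.026 FPKM. The member that rose was Mmp3 (stromelysin), from 0.294 ± 0.084 to 5.01 ± 1.08 FPKM. The median was -0.74 (camera adjusted p = 1.5e-04, adjusted p = 0.64 with an estimated correlation).

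Mitochondrially encoded mRNAs moved unequally. Of 12 tested, 6 rose and 0 fell, likewise adjusted over the list alone. The 6 include mt-Nd3 and mt-Nd4l, which held only 215 and 128 reads over all libraries. The complex I subunit mRNAs mt-Nd2 and mt-Nd1 rose from 355 ± 8.95 to 1876 ± 290 FPKM and from 866 ± 278 to 4094 ± 471 FPKM, and mt-Cytb, a complex III subunit, from 791 ± 263 to 3315 ± 377 FPKM. The rise of mt-Nd4 was a log2 fold change of 1.17. By contrast mt-Co1 had a log2 fold change of 0.00. The mRNAs mt-Co2, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l have annotated copies nearly identical in sequence that held at least 73.2% as many reads as they did, so their levels are uncertain, and they stood higher in AlCl3 2 than in AlCl3 1 and AlCl3 3. The list median was 0.79 (camera adjusted p = 0.043, adjusted p = 0.64 with an estimated correlation). The call was lost without control 3 (0.094) or AlCl3 2 (0.12), with a mean FPKM of at least 5 (0.091), under median-ratio scaling (0.062) and after removal of the GC and length trend (0.16).

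**Figure D3:**
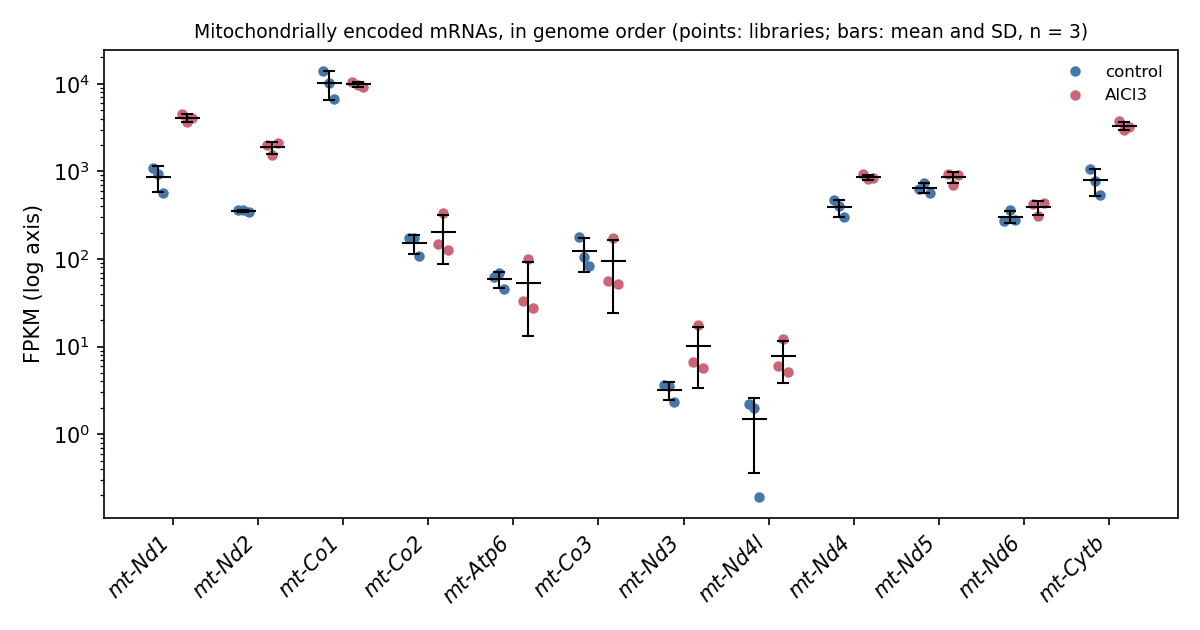
FPKM of 12 mitochondrially encoded mRNAs on a log axis, in genome order, in the 3 control and 3 AlCl3 libraries, with points for libraries and bars for the mean and SD. The 3 AlCl3 values of mt-Nd1, mt-Nd2 and mt-Cytb lie above the 3 control values, and those of mt-Co1 lie within the control range.

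Of 73 nuclear-encoded oxidative phosphorylation genes 19 fell and 11 rose, or 17 and 9 adjusted over the list alone (median -0.08, camera adjusted p = 0.41). Uqcrc2 of complex III rose from 19.0 ± 2.63 to 65.2 ± 4.04 FPKM and Ndufs1 of complex I by a log2 fold change of 1.60, while Ndufa6 fell from 256 ± 52.1 to 81.5 ± 15.1 FPKM and Ndufb4 by 1.40 on the log2 scale. Among the 36 Slc25 carriers tested, 14 rose and 15 fell, or 14 and 17 adjusted over the list alone (median -0.23, camera adjusted p = 0.44). Apart from Slc25a5, the dicarboxylate carrier gene Slc25a10 rose from 4.62 ± 0.421 to 14.9 ± 1.47 FPKM, while Slc25a42, a coenzyme A carrier gene, and the mitoferrin gene Slc25a28 fell by 1.60 and 1.33 on the log2 scale.

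NRF2 and antioxidant genes rose in 14 of 25 cases and fell in 3, also when adjusted over the list alone (median 0.53, camera adjusted p = 0.069, adjusted p = 0.54 with an estimated correlation). Without control 1 the list passed (camera adjusted p = 0.046), as it did with no filter (0.012). Besides Nqo1, Pgd of the pentose phosphate pathway rose from 15.6 ± 1.82 to 44.0 ± 3.19 FPKM and the glutathione reductase gene Gsr by a log2 fold change of 1.22. The glutathione transferase gene Gstm1 went down from 90.0 ± 10.1 to 19.8 ± 1.38 FPKM. In the list of metallothioneins and metal ion handling 6 of 14 genes rose and 1 fell, or 5 and 1 adjusted over the list alone (median 0.32, or 0.21 without AlCl3 3, camera adjusted p = 0.17). Besides Tfrc, the iron regulatory protein gene Aco1 rose by a log2 fold change of 1.29, the zinc transporter gene Slc39a10 by 0.84 and the metallothionein gene Mt1, from 97.9 ± 6.29 to 162 ± 37.6 FPKM, by 0.70.

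Cholesterol synthesis genes rose in 14 of 23 cases and fell in 5, or 15 and 5 adjusted over the list alone. Cyp51 rose from 13.7 ± 0.348 to 30.5 ± 0.862 FPKM, Idi1 by a log2 fold change of 1.37 and Insig1, a sterol sensor gene, by 1.13. Acat2 rose by 1.38, but it overlaps Tcp1, which held 8841 reads in controls and 35998 in AlCl3. The list median was 0.79 (camera adjusted p = 0.026, adjusted p = 0.64 with an estimated correlation). Of 29 glycolysis and hypoxia genes 12 rose and 5 fell, also when adjusted over the list alone (median 0.33, or 0.21 without AlCl3 2, camera adjusted p = 0.31). Pgk1 rose from 276 ± 30.6 to 594 ± 12.9 FPKM, while Pfkm, Pfkfb3 and Ndrg1 fell by 1.10, 0.85 and 1.29 on the log2 scale. In the autophagy and lysosome list 12 of 27 genes fell and 8 rose, or 13 and 8 adjusted over the list alone (camera adjusted p = 0.14). Gabarapl1 fell from 100.5 ± 4.74 to 27.4 ± 2.27 FPKM, Map1lc3a by 1.62 (-0.91 after removal of the GC and length trend) and Hexa by 1.09 on the log2 scale, and the cathepsin gene Ctsl rose by a log2 fold change of 1.28.

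Cytosolic ribosomal protein genes fell in 31 of 77 cases and rose in 10, or 30 and 9 adjusted over the list alone. Rps14 fell from 975 ± 66.8 to 393 ± 52.9 FPKM and Rps27 from 466 ± 47.5 to 204 ± 22.8 FPKM, while Rpl6 rose from 165 ± 45.4 to 637 ± 26.9 FPKM. Rpl6l, annotated as a processed pseudogene but counted in the list by its symbol, rose by a log2 fold change of 1.77. Rpl6 and Rpl6l are near copies of each other, as are Rps27 and Rps27rt, so their reads are not fully separable. The median was -0.37 (camera adjusted p = 0.019, adjusted p = 0.79 with an estimated correlation). The call was lost without control 1 (median -0.22, adjusted p = 0.19) or AlCl3 3 (-0.28, 0.060) and under quantile normalization (-0.17, 0.10). The list did not pass in fry either (fry adjusted p = 0.14).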

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

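Removal of the GC and length trend and voom on recovered reads were chosen after seeing the data, and the other alternatives before. Slc25a5 was higher and past the threshold in all 15 alternatives, with log2 fold changes of 2.65 to 2.94. Of the 107 named genes, 101 kept direction and side of the threshold in every alternative run for them, and 5 lost their call in at least 1. Most named genes were chosen for large changes or small p in these same libraries, which favours stable calls. An added limit of 1 on the absolute log2 fold change left 2387 genes, 1207 higher and 1180 lower, by construction. Leaving out single libraries gave 5792 (without AlCl3 1) to 7052 (without AlCl3 2) genes, and array weights gave 9610, in a fit that warned it had not converged. Rescaling to TPM moved the median of all genes by 0.12 (log2) and gave 6443 genes, 58.1% of them higher against 50.8%. With the GC and length trend removed, 7428 genes passed, 5870 of them shared in direction and 17 opposite, and voom gave 7008. Lists past the threshold numbered 0 in camera with an estimated correlation, 15 in fry, 6 with the GC and length trend removed, and 8 to 10 without single libraries. Among the named genes and the fixed gene lists, the direction of the test turned for Cd68 and the oxidative phosphorylation and interferon lists, which had not passed, and the cause was not tested. Without single libraries the log2 fold change of Cd68 ranged from -0.0498 to 0.144 and the oxidative phosphorylation median from -0.189 to 0.0700. The interferon list turned lower in camera with a mean FPKM of at least 5 (median 0.0673), without the GC and length trend (0.0799) and without control 2 or AlCl3 1 (medians from 0.0523 to 0.135 over libraries left out). The median alone changed sign, against the direction in camera, for the p53 targets and apoptosis list with a mean FPKM of at least 5 (0.127), for nuclear-encoded oxidative phosphorylation after rescaling to TPM (0.037), without AlCl3 3 (0.021) and without the GC and length trend (0.0050), and for the type I interferon response with voom (-0.0099), none of which passed. Whether the replicate numbers pair the libraries is not established, since the labels do not say. Deviations of same-numbered libraries correlated at 0.20, 0.097 and 0.39 across genes, and 5 of 6 libraries correlated best with their own number, a hint from the data and not from the design. With the replicate block 7375 genes passed, 3778 higher and 3597 lower. Depth limits mainly the genes under 200 reads, where most simulated false calls fell.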

Other observations

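Quantile normalization and the splits of the libraries were planned but read as tests of explanations only after their results were seen, and all other tests, the gene lists of this part and the genes it names for the first time were chosen after the results were seen. Genes of nucleolar ribosome biogenesis, many of them known MYC targets, rose in 26 of 28 cases and fell in 0. Ncl (nucleolin) went from 39.0 ± 4.31 to 128 ± 27.7 FPKM and Nop58, a box C/D snoRNP protein gene, from 9.39 ± 1.99 to 30.1 ± 2.74 FPKM. The list median was 1.11 (camera adjusted p = 5.2e-08 over 4 added lists, adjusted p = 0.021 with an estimated correlation). All 8 subunit genes of the CCT chaperonin, which folds actin and tubulin, rose, with a median of 1.86 (camera adjusted p = 2.7e-05, adjusted p = 0.19 with an estimated correlation). Cct3 rose from 26.4 ± 2.01 to 128 ± 8.85 FPKM and Cct5 from 91.6 ± 13.1 to 353 ± 18.8 FPKM. The added lists were not run under the alternatives, and their p-values do not account for their choice after the results were seen.

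Substrates of nonsense-mediated decay rose in 5 of 19 cases and fell in 7 (median -0.13, camera adjusted p = 0.63, fry adjusted p = 0.012). Of that list, the noncoding RNAs Zfas1 and Gas5 fell from 181 ± 52.8 to 42.5 ± 3.47 FPKM and from 179 ± 50.2 to 50.4 ± 1.67 FPKM, while Tra2a and Upp1 rose by log2 fold changes of 1.63 and 1.54.

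The breadth of the difference, 6869 genes, was set against technical explanations. A trend of fold changes with GC content (Spearman correlation across genes -0.34, genes not being independent replicates) was seen between groups and between replicates, but after its removal with that of length 5870 of the calls remained in the same direction. A few abundant genes taking reads from the rest is argued against by quantile normalization, after which 6732 calls remained. Of the 10 splits of the 6 libraries, 1 gave as many genes, the real one, and the highest of the others gave 0, while 2 gave as many gene lists as the real 9, the highest of the others giving 10, and 10 splits are too few for a share under 0.05. A difference in handling, collection or library batch that goes with the group cannot be told apart from AlCl3, since the labels give no batch and the component that separates the groups holds 83.8% of the variance.

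The unequal movement of mitochondrially encoded mRNAs, from a rise in mt-Nd2 to no call in mt-Co1, could come from reads shared with nuclear copies. The SD of the 12 log2 ratios was 1.15 without and 1.08 with the reads of annotated copies added. It could hardly fall, since copies of 7 mRNAs held few reads. Among mRNAs without annotated copies, log2 ratios were 2.29 for mt-Nd1, 2.12 for mt-Cytb and 0.36 for mt-Nd6. This argues against annotated copies as the cause of the difference between these mRNAs. The SD was 1.05 before and 1.04 after removal of the GC and length trend. That cannot decide on the trend, since GC content ran only from 33.0% to 41.1% and removal shifted the mRNAs nearly alike. Copies of mt-Nd1, mt-Nd2, mt-Cytb, mt-Co1, mt-Nd4, mt-Nd5 and mt-Nd6 held under 2% as many reads as these mRNAs. Copies missing from the annotation and differences in RNA selection between libraries were not tested, and a response of mitochondrial transcripts to AlCl3 stays open.

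The rise of cell cycle and nucleolar genes raised the hypothesis that control cultures were denser and held back by contact. Targets of YAP and TEAD, which fall under contact inhibition, should then be lower in controls, but their median was -0.66, 11 of 19 falling and 2 rising in AlCl3 (fry adjusted p = 0.0054, camera adjusted p = 0.53 with an estimated correlation). Amotl2 of that list fell from 130 ± 18.7 to 21.2 ± 1.94 FPKM. Higher Myc mRNA is argued against by Myc itself, with a log2 fold change of -1.21, and the GC and length trend by the cell cycle median of 1.43 after its removal. A growth response to AlCl3 and other differences in culture state, a higher density in AlCl3 among them, were not tested and stay open.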
